A study of Danio rerio with 23 samples.

How the data were processed

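RNA from the ovaries of wild-type and nr3c1 mutant fish of 2 ages, 3 and 6 months, was sequenced in 23 libraries. RNA was extracted with a column kit and libraries were made after capture of polyadenylated RNA, per the labels' protocols. The deposited files hold 1 estimated count per transcript and library. The submitters' processing notes name kallisto 0.48.0, a tool that assigns reads to annotated transcripts without full alignment, and the build GRCz11. Its estimated counts split reads that fit several transcripts between them in proportion, so 75.7% of the nonzero values were not whole numbers, and transcripts of 1 gene or of near-identical genes share reads. Strand setting, annotation release and read filters are not given in the sources used here. Each file listed the same 57775 Ensembl transcript identifiers in the same order, of which 3731 had a value of 0 in every library.

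Samples were grouped by the genotype and age in their titles, and library numbers were taken from the titles. The labels do not say whether each library came from a separate fish. GRKO library 4 at 3 months has a title and library name of the mutant but the genotype field of the wild type; it was kept in GRKO by its title, and leaving it out or counting it as WT were alternatives. Pairs of libraries within a group differed far beyond counting noise (chi-square per degree of freedom of 28.3 or more over transcripts with 20 or more counts in the pair), so none was treated as a repeat of another.

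The estimated counts were rounded to whole numbers and tested per transcript. The tests had been planned for genes. The files list transcripts, and 0 of the identifiers matched the gene name table used here, so 41 gene lists fixed before the data were examined, the transcripts of the targeted gene, tests with TPM values and covariates made from gene lists were not analysed here. The main test was edgeR 4.0.16 (quasi-likelihood test with robust estimation, TMM factors, R 4.3.3) on all 23 libraries with 1 mean per group, after edgeR's default expression filter (a minimum count of 10 and a total of 15), which kept 30849 transcripts. These held a median of 99.87% of a library's counts. P-values were adjusted by the Benjamini-Hochberg method over all tested transcripts, with a threshold of 0.05. The comparisons were GRKO against WT at each age, 6 against 3 months in each genotype, and the interaction of genotype and age. A standard error is the log2 fold change divided by the square root of the test's F. Where a group had a rounded count of 0 in every library, the fold is a lower bound from the other group's mean and 3 counts over the empty group, which covers counting error only. CPM values use TMM-scaled library sizes, and principal components and correlations between libraries use log2 CPM with a prior count of 2.

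The rule for naming items, set before the data were examined, asked for genes with the largest fold among those past the threshold, at 1 CPM or more on average over the groups compared and with every library of the first group on the same side of the median of the other. As the identifiers carry no gene names, at most 2 transcripts that rose and 2 that fell by this rule are named per comparison, and its parts on named genes and lists could not be applied. None of those named by the rule had whole estimated counts in every library. Their folds may therefore include reads split with other transcripts.

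The test was checked on simulated counts drawn from the means, dispersions and library sizes of the 30849 transcripts. Per comparison, 100 transcripts were changed 2-fold and 100 were changed 4-fold, all with a mean of 1 CPM or more. Of these the test recovered 32% and 66% for GRKO against WT at 3 months and 30% and 65% at 6 months. It recovered 38% and 59% for age in WT, 47% and 80% for age in GRKO and 25% and 50% for the interaction. In the same order there were 1, 5, 3, 8 and 7 false calls. No transcript under 1 CPM was changed, so recovery there was not measured. Small folds were thus often missed at this number of libraries.

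Alternatives set before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma 3.58.1 (voom with sample quality weights), no robust estimation, no filter and a filter of 1 CPM in 5 libraries, only the groups compared, the library number as a block, both treatments of GRKO library 4, a fold threshold and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out WT libraries 2 and 6 at 3 months, leaving out GRKO libraries 10 and 12 at 6 months, thinning every library to the smallest total and keeping only transcripts with whole estimated counts. Whether a count of calls could arise by chance was checked by regrouping the same libraries at random, 100 groupings per comparison with the real one included; for the interaction the ages were shuffled within each genotype. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.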

Results

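Ovaries of female zebrafish (Danio rerio) were profiled by RNA-seq of polyadenylated RNA in 23 libraries. The fish were wild type (WT) or carried a loss of nr3c1 in the whole body. This gene encodes the glucocorticoid receptor, the nuclear receptor through which cortisol acts on transcription, and the mutants are called GRKO here. They were sampled at 3 and 6 months of age, and the question of the series is what part loss of the receptor plays in faster ageing of the ovary. The groups held 5 WT libraries at 3 months, 6 WT libraries at 6 months, 6 GRKO libraries at 3 months and 6 GRKO libraries at 6 months. Libraries are named by their group and the number in their titles. The labels do not say that each library came from a separate fish, so p-values measure the spread between these libraries, part of which may be technical. The deposited values were estimated counts for 57775 transcripts, and each library summed to 29489146 to 39785753 counts. Totals ranged from 33606803 to 39785753 in WT at 3 months, from 29489146 to 35535800 in WT at 6 months, from 30452427 to 37985230 in GRKO at 3 months and from 31242818 to 37292796 in GRKO at 6 months. The files do not pair transcript identifiers with genes, so transcripts are given by identifier, and the transcripts of nr3c1 itself were not analysed here.

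Genotype was the main visible division among the libraries, with exceptions among the WT libraries that were most marked at 3 months. The 12 GRKO libraries lay at or below 8.89 on the first principal component, which held 28.8% of the variance of log2 CPM. The 6 WT libraries at 6 months lay between 24.9 and 145 on it, and WT libraries 10, 12 and 13 at 3 months lay at 149, 156 and 184. WT libraries 2 and 6 at 3 months lay at -120 and -110, among the GRKO libraries, but stood apart from them on the second component (12.7% of the variance) at -189 and -174. Across transcripts, the median correlation of these 2 libraries with GRKO libraries of the same age was 0.870 and 0.882, against 0.782 and 0.798 with the other WT libraries of that age. WT libraries 1 and 2 at 6 months lay toward them, at 28.8 and 24.9 on the first component and -75.1 and -85.9 on the second. They correlated at 0.861 to 0.874 with WT libraries 2 and 6 at 3 months. The other WT libraries at 6 months did so at 0.798 to 0.831. The 6 GRKO libraries at 3 months were the most alike, with correlations between pairs of 0.924 to 0.946. Pairs of WT libraries at 3 months ranged from 0.7645 to 0.939.

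**Figure D1:**
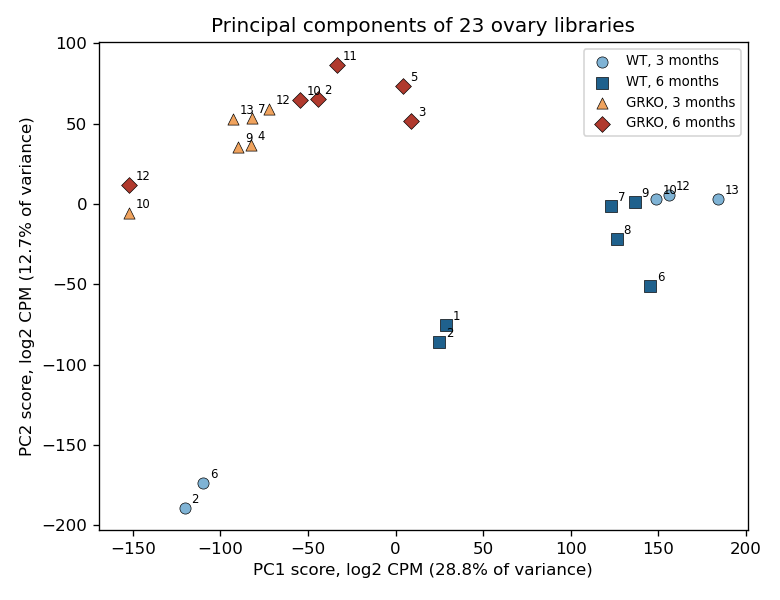
Scores of the 23 ovary libraries on the first (horizontal axis) and second (vertical axis) principal components of log2 CPM over 30849 transcripts, 1 point per library, with colour and shape for the group and the library number beside each point. WT libraries 2 and 6 at 3 months lie at -189 and -174 on the second component, while the other 3 libraries of their group lie near 0 on it and at 149 to 184 on the first.

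At 3 months, loss of the receptor went with lower levels of more transcripts than higher levels. Of 30849 transcripts tested, 2588 differed between GRKO and WT (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with 820 higher and 1768 lower in GRKO. The lower group also moved further. Its median log2 fold change was -2.05, and 671 of its members were at least 8-fold lower. The higher group had a median of 1.00, and 123 members were at least 8-fold higher. In the lower group 273 transcripts had a count of 0 in all 6 GRKO libraries, and in the higher group 29 had a count of 0 in all 5 WT libraries. Setting these at the fold that 3 counts over the group would allow left both medians as they were.

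The direction of change at 3 months differed with abundance. Among transcripts over 100 CPM on average, 96 of the 143 called were higher in GRKO. Among those of 1 to 10 CPM, 794 of the 1046 called were lower. The transcripts named here had a count of 0 in every library of 1 genotype at 3 months. Like all transcripts named by the rule, they had fractional estimated counts in 1 library or more. Whether a count of 0 came from reads assigned to another transcript was not tested. ENSDART00000186830.1 had a count of 0 in all 5 WT libraries and 30.6 ± 18.8 CPM (SD, n = 6) in GRKO, at least 1830-fold higher when the WT group is set at 3 counts over the group (adjusted p = 0.00953). ENSDART00000184092.1 also had a count of 0 in all 5 WT libraries and stood at 18.2 ± 2.6 CPM (n = 6) in GRKO, at least 1080-fold higher (adjusted p = 0.00319). In the opposite direction, ENSDART00000183479.1 had a count of 0 in all 6 GRKO libraries and 64.3 ± 59.4 CPM (n = 5) in WT, at least 4260-fold lower in GRKO (adjusted p = 0.0172). ENSDART00000181220.1 had a count of 0 in all 6 GRKO libraries and 57.8 ± 55.8 CPM (n = 5) in WT, at least 3830-fold lower in GRKO (adjusted p = 0.0181). Both of the latter also had a count of 0 in WT libraries 2 and 6, so that only WT libraries 10, 12 and 13 set their difference. At 6 months none of these 4 transcripts passed the test, with adjusted p = 0.369, 0.0732, 0.675 and 0.495 in the order given, and WT library 7 of that age held 51 CPM of ENSDART00000186830.1. Their interactions with age did not pass either, with adjusted p = 0.403, 0.448, 0.442 and 0.588.

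The same division of the young wild type ran through the lower group. Of the 671 transcripts at least 8-fold lower in GRKO, 184 (27.4%) were lower in every GRKO library than in every WT library. For 290 others, WT libraries 10, 12 and 13 lay above all GRKO libraries while WT libraries 2 and 6 did not. The higher group was more even, since 102 of the 123 transcripts at least 8-fold higher (82.9%) separated all libraries of the 2 genotypes. Over all tested transcripts, 6.21% separated the genotypes completely, where chance gives 0.433% for 5 against 6. Leaving out WT libraries 2 and 6 raised the count to 8937 transcripts (3732 higher, 5205 lower), which held 2311 of the 2588, all in the same direction; leaving out WT library 12 or 13 or GRKO library 10 alone lowered it to 1696, 1575 and 1687. The balance of directions depended on scaling, since upper-quartile factors gave 1306 higher and 1504 lower (46.5% higher, against 31.7%), and counting GRKO library 4 as WT, as its genotype label has it, left 456 transcripts.

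At 6 months the 2 genotypes differed at 1865 of 30849 transcripts, 782 higher and 1083 lower in GRKO (edgeR, adjusted p under 0.05). Lower transcripts again moved further, with a median log2 fold change of -1.74 against 1.12 for higher ones. At least 8-fold differences numbered 335 lower and 170 higher. The most extreme single difference was ENSDART00000183657.1, an abundant transcript in every WT library that was all but missing from the mutants. It stood at 649.8 ± 112 CPM (SD, n = 6) in WT at 6 months and at a rounded count of 0 in all 6 GRKO libraries of that age, at least 43400-fold lower (adjusted p = 7.02e-07). At 3 months it had 0.216 ± 0.298 CPM (n = 6) in GRKO and 554 ± 396 CPM (n = 5) in WT, a log2 fold change of -11.38 (SE 0.95, adjusted p = 2.6e-06). WT libraries 2 and 6 at 3 months carried it at 134 and 180.5 CPM, far above any GRKO library.

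ENSDART00000190261.1 had a count of 0 in all 12 GRKO libraries and 41.2 ± 22.9 CPM (n = 6) in WT at 6 months, where it was at least 2750-fold lower in GRKO (adjusted p = 0.0467). WT library 2 of that age had 0.1725 CPM of it, and at 3 months it was seen only in WT library 10, at 53.1 CPM. Its call was lost in 16 of 35 alternative settings, with adjusted p from 1.3e-14 to 0.22. Among transcripts that were higher, ENSDART00000142741.2 reached 16.7 ± 4.47 CPM (n = 6) in GRKO and a rounded count of 0 in all 6 WT libraries, at least 1160-fold higher (adjusted p = 0.00182). ENSDART00000102534.4 reached 15.9 ± 7.24 CPM (n = 6), at least 1100-fold higher (adjusted p = 0.000752). At 3 months the former stood at 15.8 ± 9.75 CPM (n = 6) in GRKO, with a count of 0 in GRKO library 10, and the latter at 4.06 ± 4.99 CPM (n = 6).

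A part of the higher group at 6 months rested on 2 libraries. Of the 170 transcripts at least 8-fold higher in GRKO, 57 (33.5%) were above every WT library in all 6 GRKO libraries, and for 55 others only GRKO libraries 10 and 12 lay above the WT range. Of the 335 at least 8-fold lower, 132 (39.4%) separated all libraries. Over all tested transcripts, 4.69% separated the genotypes at 6 months, where chance gives 0.216% for 6 against 6. Leaving out GRKO libraries 10 and 12 reduced the count from 1865 to 630, of which 599 were among the 1865; leaving out GRKO library 12 alone gave 1100 and WT library 6 alone 1209. Leaving out WT libraries 2 and 6 of the 3 months group, which share the estimate of spread, gave 3482.

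Many transcripts differed between the genotypes at both ages. Of the calls, 340 were higher in GRKO at both ages and 672 were lower at both, where independent lists of these sizes would share 20.8 and 62.1. Both lists come from 1 fit with 1 filter and a shared estimate of spread, so more than these could be shared without a common effect. None was called in opposite directions at the 2 ages, but without WT libraries 2 and 6 of the 3 months group 3 were higher then lower and 86 lower then higher. The 672 lower transcripts had median log2 fold changes of -2.16 at 3 months and -1.93 at 6 months, and 226 of them were at least 8-fold lower at both. The 340 higher transcripts had medians of 1.05 and 1.01, and 50 were at least 8-fold higher at both. Together, the 672 made up 1.4% ± 0.16 (SD, n = 5) of the counts in WT and 0.574% ± 0.011 (n = 6) in GRKO at 3 months, and 1.36% ± 0.041 (n = 6) and 0.606% ± 0.034 (n = 6) at 6 months. The 340 made up 1.76% ± 0.11 (n = 5) in WT and 2.86% ± 0.12 (n = 6) in GRKO at 3 months, and 1.66% ± 0.12 (n = 6) and 2.6% ± 0.31 (n = 6) at 6 months. WT libraries 2 and 6 went with the other WT libraries here, at 1.21% and 1.28% for the lower set and 1.76% and 1.91% for the higher set. These sets were chosen for the difference, so the shares describe its size and do not test it.

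Transcripts called at 1 age mostly had a fold change of the same sign at the other. Of the 2588 called at 3 months, 97.4% had a fold change of the same sign at 6 months, and of the 1865 called at 6 months, 94.2% had the same sign at 3 months. Over all 30849 transcripts the 2 genotype effects correlated at r = 0.572 (Spearman's rho 0.599), across transcripts, which are not independent replicates. No library enters both comparisons. With at least 1 CPM in every library of 1 genotype and a count of 0 in every library of the other, over both ages, 2 transcripts were seen only in GRKO and 5 only in WT.

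**Figure D2:**
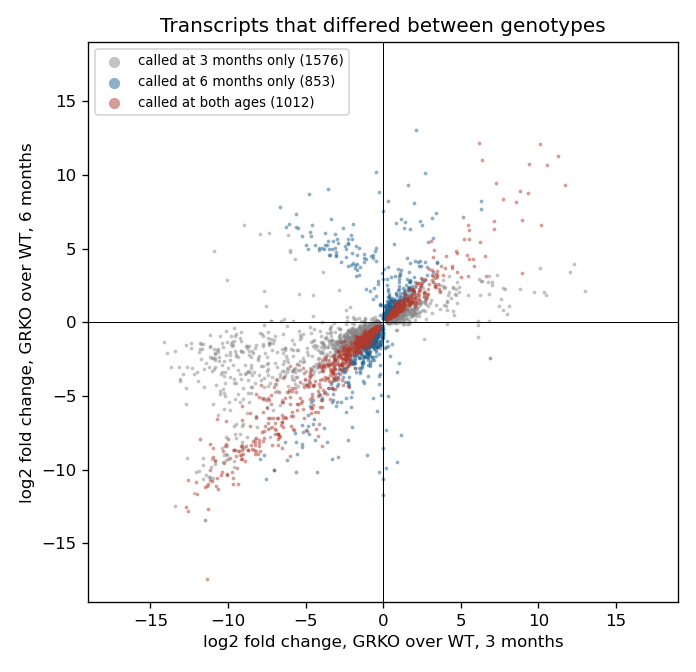
log2 fold change of GRKO over WT at 3 months (horizontal axis) and at 6 months (vertical axis), 1 point for each of the transcripts called at 3 months only, at 6 months only or at both ages (edgeR, adjusted p under 0.05). Transcripts called at both ages lie at the lower left (672) and upper right (340), and a set called at 6 months only lies at the upper left.

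Age changed few transcripts past the test in either genotype. Between 3 and 6 months, 3 of 30849 transcripts differed in WT, 2 higher and 1 lower (edgeR, adjusted p under 0.05). ENSDART00000172366.2 was seen in all 6 WT libraries at 6 months, at 5.86 ± 1.52 CPM, and had a count of 0 in all other 17 libraries. It was at least 350-fold higher at 6 than at 3 months in WT (adjusted p = 0.00315). ENSDART00000053761.7 fell from 85.2 ± 10.1 CPM (n = 5) to 52.2 ± 4.27 CPM (n = 6), a log2 fold change of -0.71 (SE 0.12, adjusted p = 0.0479). This call was lost in 27 of 36 alternative settings, with adjusted p from 5.48e-06 to 0.675. In GRKO the same transcript was at 58.1 ± 7.75 CPM at 3 months and 65.3 ± 11.5 CPM at 6 months (n = 6 each). The remaining call, ENSDART00000081946.5, lay under the minimum of 1 CPM over both groups for naming and was chosen after its values were seen. It rose from 0.0499 ± 0.0461 CPM (n = 5) to 1.34 ± 0.70 CPM (n = 6), a log2 fold change of 4.65 (SE 0.62, adjusted p = 0.00315). At an unadjusted p under 0.05, 3477 transcripts differed, where chance gives 1542. DESeq2 called 433 (168 higher, 265 lower), with the balance turned, and the edgeR count was 58 without WT libraries 2 and 6 of the 3 months group, 26 without WT library 10 of that group, and 5 and 7 without WT libraries 1 and 8 of the 6 months group.

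In GRKO, 5 transcripts differed between 6 and 3 months, 1 higher and 4 lower at 6 months (edgeR, adjusted p under 0.05). ENSDART00000053152.6 rose from 9.04 ± 0.552 CPM to 15.4 ± 2.1 CPM (n = 6 each), a log2 fold change of 0.76 (SE 0.12, adjusted p = 0.0142). In WT it stood at 14.0 ± 0.429 CPM (n = 5) and 17.9 ± 3.1 CPM (n = 6). Of the 4 that fell, 2 are named. ENSDART00000160320.2 fell from 11.8 ± 9.56 CPM to 0.0603 ± 0.0425 CPM (n = 6 each), a log2 fold change of -7.54 (SE 1.02, adjusted p = 0.00418). ENSDART00000126857.3 fell from 6.38 ± 3.97 CPM to 0.1225 ± 0.0502 CPM (n = 6 each), a log2 fold change of -5.67 (SE 0.64, adjusted p = 0.000394). GRKO library 4 at 3 months, titled GRKO but with the genotype field of the wild type, had 0.0293 and 0.263 CPM of these 2. These were the levels of the GRKO libraries at 6 months or little above them. The 5 WT libraries at 3 months had 7.24 to 63.3 and 4.42 to 17.9 CPM. At an unadjusted p under 0.05, 3179 transcripts differed in GRKO, and DESeq2 called 772, of which 566 were higher and 206 lower at 6 months (73.3% higher, against 20% with edgeR), so the balance of directions turned with the tool. The count was 15 without GRKO library 13 of the 3 months group, 2 without library 10 of that group, and 3 without libraries 7 or 9 of that group or without libraries 3, 5, 10 or 11 of the 6 months group.

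For the effect of genotype between ages, 2 transcripts passed the test of the interaction, both negative, and these were the 2 named above that fell with age in GRKO. In WT, ENSDART00000160320.2 stood at 24.8 ± 24.4 CPM (n = 5) and 32.7 ± 9.93 CPM (n = 6) at the 2 ages, and its interaction was -7.94 on the log2 scale (SE 1.27, adjusted p = 0.0484). ENSDART00000126857.3 stood at 8.49 ± 5.41 CPM (n = 5) and 7.98 ± 1.65 CPM (n = 6) in WT, with an interaction of -5.58 (SE 0.81, adjusted p = 0.0258). At 6 months both were lower in GRKO, at adjusted p = 2.16e-05 and 7.25e-06, and at 3 months neither differed past the test, at adjusted p = 0.409 and 0.692. The interaction calls were lost in 26 and 20 of 35 alternative settings, with adjusted p from 9.92e-10 to 0.488 and from 6.82e-10 to 0.326. The test could not judge some transcripts with a count of 0 in every library of several groups. ENSDART00000172366.2, seen only in WT at 6 months, had an interaction of -10.65 with an SE of 7870 and did not pass. Few calls therefore do not show that the genotype effect was alike at both ages. An unadjusted p under 0.05 for the interaction was reached by 1490 transcripts, where chance gives 1542, and DESeq2 called 403 (342 positive, 61 negative), so the balance of signs turned with the tool. The count fell to 0 or 1 when any library other than WT library 6 and GRKO library 4 at 3 months and WT library 2 at 6 months was left out alone, fell to 0 without GRKO libraries 10 and 12 of the 6 months group, and rose to 140 without WT libraries 2 and 6 of the 3 months group.

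**Figure D3:**
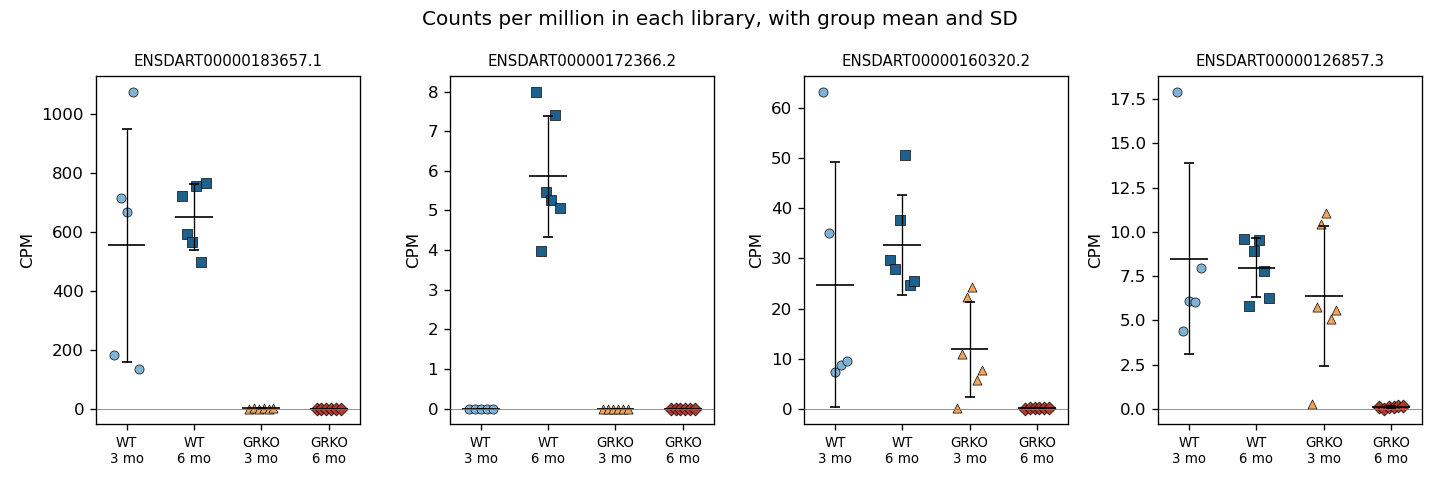
CPM (vertical axis) of 4 transcripts in each of the 23 libraries by genotype and age (horizontal axis), 1 point per library, with the group mean as a horizontal line and its SD as a bar. ENSDART00000183657.1 was near 0 in all GRKO libraries, ENSDART00000172366.2 was seen only in WT at 6 months, and ENSDART00000160320.2 and ENSDART00000126857.3 were near 0 in GRKO at 6 months and in 1 GRKO library at 3 months.

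If the young mutant ovary resembled the older wild-type ovary, the genotype effect at 3 months would go with the age effect in WT. Across 30849 transcripts the 2 correlated at r = 0.28 (Spearman's rho 0.134). Both use the same 5 WT libraries at 3 months, and simulated groups with no change gave r = 0.551 on average over 20 runs (range 0.534 to 0.577). The covariance was 0.452, against 0.449 in the simulated groups (range 0.421 to 0.483), a difference of 0.00247. Regrouping the labels of the 17 libraries 100 times gave, for differences of mean log2 CPM, a mean covariance of 0.254 (range -0.0273 to 1.11), a range that holds the 0.151 observed. With the 5 shared libraries split so that no library served both comparisons, r averaged 0.00562 over 20 splits (range -0.503 to 0.191). The result depended on WT libraries 2 and 6 of the 3 months group. Without them r was 0.597, where simulated groups with no change gave 0.691 on average (range 0.676 to 0.703), and the covariance was 1.78 against 0.883 (range 0.84 to 0.923), a difference of 0.896. The 3 shared libraries that remained were too few to be split. Simulated transcripts varied independently of each other, so the simulated ranges leave out structure shared within libraries and are too narrow. Regrouping of labels was not repeated without these 2 libraries, so no resemblance is read from the difference of 0.896. With GRKO library 4 counted as WT, r was 0.14. The age effects in WT and in GRKO, which share no library, correlated at r = -0.00907 (Spearman's rho 0.291). Leaving out single libraries moved this r between -0.0978 and 0.142, so its sign rested on single libraries.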

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

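The tests of mixed GRKO ovary, of carry-over, of ages shuffled within genotype and of reads shared between transcripts were chosen after the results they bear on were seen, as were leaving out WT libraries 2 and 6, thinning and the set of 66 transcripts.

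WT libraries 2 and 6 at 3 months stood apart from libraries 10, 12 and 13 of their group and were nearer the GRKO libraries on the first principal component. A wrong genotype label is argued against, since of 876 transcripts that separated the genotypes at 6 months, 36.3% and 37.3% placed libraries 2 and 6 nearer the GRKO mean, against 14.3% to 22.9% for the other WT libraries and 88.8% to 94.6% for the GRKO libraries of that age. After thinning to 29489146 counts their median correlations with libraries 10, 12 and 13 were 0.781 and 0.795, below the lowest among those 3 (0.915), which argues against depth. GRKO ovary at a share of 10% or more in the 2 libraries is argued against by 15 transcripts at 1 CPM or more in all 12 GRKO libraries and low in WT at 6 months (at most 5% of the GRKO mean), whose upper quartiles in libraries 2 and 6 were 3.81% and 2.84% of the GRKO mean. The stage or cell makeup of the ovaries and an unrecorded batch were not tested and stay open.

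The count of 2588 transcripts at 3 months was reached by 4 of 100 groupings of the same 11 libraries, the real one included. The highest other grouping gave 4389. A count of 4 lies just under the bound set beforehand for excluding chance. The 100 were drawn from 462 possible groupings, so the margin is narrow and chance is not firmly excluded. The 3 groupings that gave more kept WT libraries 2 and 6 on 1 side and 10, 12 and 13 on the other, which points to a structure within the WT group, but others with that division gave 0 to 2366, so the place of the GRKO libraries mattered too. Not all calls followed the division within WT. Of the 820 higher transcripts 579, and of the 1768 lower 734, separated every GRKO library from every WT library, 2 and 6 included. A further 451 of the lower followed the division within WT. These transcripts were called for the same difference, and such counts were not made for the other groupings, so they do not exclude chance. For the calls that did not separate all libraries, the part of the structure within WT also stays open. Leaving out libraries 2 and 6 gave 8937, but this sets only libraries 10, 12 and 13 against GRKO. The rise, contrary to the bound set beforehand, therefore excludes nothing. Depth and shared reads were argued against, with 2619 calls after thinning, and 8.95% called among transcripts with whole estimated counts in all libraries against 8.31% among the others. The genotype stays a hypothesis, since the labels give no batches and an unrecorded batch that follows the groups was not tested.

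GRKO libraries 10 and 12 at 6 months shared a set of 66 transcripts that were called and at least 2-fold higher in GRKO at 6 months and at least 2-fold lower at 3 months. The set summed to 3150 and 5740 CPM in these 2 libraries and to 25.8 to 142 CPM in the other 4 of the group, and to 593 and 405 CPM in WT libraries 10 and 12 at 3 months and 27.9 to 76.7 CPM in the other 3. Carry-over from GRKO would bring the 15 GRKO transcripts above in a like ratio to GRKO library 12. The set of 66 stood at 10.3% of its level in WT library 10 and at 7.06% in WT library 12. The 15 had medians of 0.584% and 0% there and upper quartiles of 5.5% and 0.899%. In the same order, 7 and 9 of the 15 had a count of 0. These values argue against carry-over at those ratios, although the upper quartile in WT library 10 missed the bound set for excluding it. RNA of 1 common source, such as a neighbouring tissue, needs a common ratio; correlations across the set ranged from 0.731 (GRKO library 12 with WT library 12) to 0.957 (GRKO libraries 10 and 12), below the 0.8 set beforehand in some pairs and above the 0.5 that would exclude it. RNA of 1 common source stays open, as does a biological difference between the ovaries, which was not tested.

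The test of the interaction passed for 2 transcripts, with log2 values of -7.94 for ENSDART00000160320.2 and -5.58 for ENSDART00000126857.3. With the ages shuffled within each genotype, 15 of 100 groupings gave as many calls, the real one included, so chance could not be excluded, and the highest other gave 806, which points to a structure of the samples. Single libraries also lay far from their group. Of 40 groups of library measures tested 3 had such a library, where chance gives about 1 in 20 for normally distributed values. Of 39 groups of CPM values 8 did. These transcripts were named for extreme folds and often had counts of 0, so the rate of 1 in 20 does not apply to them. GRKO library 10 at 3 months had -152 on the first principal component, where the others had -92.9 to -72, and -5.53 on the second, where they had 35.7 to 59. GRKO library 12 at 6 months had a distance of 1.45 (root mean square of log2 CPM) from the mean of its group's other libraries, which had 0.97 to 1.09. WT library 7 at 6 months held 51 CPM of ENSDART00000186830.1 (others 0 to 14.8) and 4.96 CPM of ENSDART00000184092.1 (others 0 to 0.0288). GRKO library 5 at 6 months held 65.1 CPM of ENSDART00000183479.1 (others 0 to 18.3) and 38 CPM of ENSDART00000181220.1 (others 0 to 6.12). WT libraries at 3 months with a lone high value were library 13 for ENSDART00000142741.2 (1.09 CPM), library 10 for ENSDART00000190261.1 (53.1 CPM) and library 6 for ENSDART00000126857.3 (17.9 CPM, others 4.42 to 7.96). GRKO library 3 at 6 months had the lowest value of ENSDART00000126857.3, 0.0257 CPM (others 0.124 to 0.169).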

How the results depend on the processing

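Leaving out pairs of libraries, thinning and keeping only whole estimated counts were chosen after seeing the data. Counts are given in the order GRKO against WT at 3 months (2588), at 6 months (1865), age in WT (3), age in GRKO (5) and interaction (2); the cause was not tested except where fewer transcripts or libraries entered. RLE factors, upper-quartile factors, no robust estimation and a filter of 1 CPM in 5 libraries kept all 5 counts within 1.5 times. DESeq2 gave 4221, 3568, 433, 772 and 403. Limma voom with quality weights gave 10197, 21, 712 and 1 for the first and last 3, with weights of 0.141 and 0.19 for WT libraries 2 and 6. Without those 2 libraries the counts were 8937, 3482, 58, 31 and 140. Without GRKO libraries 10 and 12 they were 630, 2 and 0 at 6 months, for age in GRKO and for the interaction. Only whole estimated counts gave 423, 434, 0, 0 and 0 from 3991 transcripts. A fold of 2 or more gave 1695, 1223 and 3 (age in GRKO). Only the 2 groups compared gave 1447 at 3 months and 1 for each age comparison. GRKO library 4 as WT gave 456, 1 and 3 (3 months and both age comparisons). No filter, and thinning, gave 1 for the interaction. Leaving out each library gave 1575 to 3593, 1100 to 2307, 2 to 26, 2 to 15 and 0 to 3.

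The library number as a replicate block (16 coefficients, 7 residual degrees of freedom) gave 253, 17, 0 and 0 for both genotype comparisons, age in WT and the interaction, and 6 for age in GRKO (5 higher, 1 lower, 1 of them among the 5 calls without the block). The labels do not say that equal numbers share a tank or day. Same-numbered libraries deviated from their group means with correlations of -0.292 to 0.359 (median -0.017, 13 pairs), and 1 of 17 libraries correlated best with its own number, so the numbers were not taken to pair the libraries.

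Correlations moved as follows. For genotype at 3 months with age in WT (0.28), 1 CPM in 5 libraries gave 0.233, GRKO library 4 as WT 0.14, no WT libraries 2 and 6 0.597, Spearman 0.134, called transcripts only 0.453, split controls 0.00562, and the block reversed it to -0.138; single libraries left out gave 0.228 to 0.389. For the genotype effects at both ages (0.572) the same settings gave 0.634, 0.544, 0.498, 0.599 and 0.706, and single libraries 0.492 to 0.61. For the age effects (-0.00907) they gave 0.0141, 0.0233, -0.176, 0.291 and 0.327, the block 0.0182, and single libraries -0.0978 to 0.142, so its sign was not settled. Over the named transcripts, 419 of 533 alternative values kept their call, 114 lost it and 0 changed sign. TPM values, gene lists and covariates made from them were not run. Thinning to the smallest total gave 2619 calls at 3 months, and lower depths were not tested.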

Other observations

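The test of the spread between libraries, the pairs of libraries, the set of 90, the 66 transcripts within it and leaving out WT libraries 2 and 6 were chosen after the values were seen.

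The number of transcripts at 1 CPM or more in 1 library and at a rounded count of 0 in another was large within the young wild type. Whether counts of 0 came from reads assigned to other transcripts was not tested. Pairs of WT libraries 2 or 6 with 10, 12 or 13 at 3 months differed at 1606 to 1841 transcripts. Libraries 2 and 6 differed from each other at 459, and pairs among 10, 12 and 13 at 403 to 538. Pairs of a WT and a GRKO library at 3 months had a median of 1169.5 (range 731 to 1728), and such pairs at 6 months a median of 906 (range 698 to 1874). GRKO pairs at 3 months had a median of 491 (range 354 to 591), WT pairs at 6 months 791 (411 to 991) and GRKO pairs at 6 months 584 (444 to 1127).

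At 6 months 90 transcripts were higher in GRKO while their fold change at 3 months was negative, with median log2 fold changes of 4.85 and -2.17. The choice of opposite signs itself favours a small interaction p, so no interaction test is read from them, whether with all libraries (0 of the 90 called) or without WT libraries 2 and 6 (37 called, and 30 called lower at 3 months). In 65 of the 66 with at least 2-fold opposite changes, GRKO libraries 10 and 12 were the highest of their group, and in 59 WT libraries 10 and 12 were the highest of theirs at 3 months.

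For the other comparisons, 1 of 100 groupings, the real one, reached the 1865 calls at 6 months (highest other 60). A random division of these libraries could be excluded there. Regrouping takes the libraries as independent, so it cannot exclude libraries that share a fish or an unrecorded batch that follows the groups. The 5 calls for age in GRKO were also reached by 1 of 100, the real one, but the highest other gave 3. Leaving out some single libraries brought the real count to 3 or fewer, so chance is not excluded for age in GRKO. For age in WT, 24 of 100 groupings reached the 3 calls, so chance could not be excluded, and the highest gave 2726. That grouping put WT libraries 10, 12 and 13 at 3 months with libraries 6, 7 and 8 at 6 months. On its other side were WT libraries 2 and 6 at 3 months with libraries 1, 2 and 9 at 6 months. This is a structure of the samples that age does not follow.

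GRKO library 4 at 3 months, with the genotype field of the wild type, may be a wild-type library with a wrong title. Of the 876 transcripts that separated the genotypes at 6 months, 90.3% placed it nearer the GRKO mean, within the range of the other 5 GRKO libraries of its age (88.8% to 94.6%), which argues against that.

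A hypothesis was that mutant ovaries grow less alike with age. The mean distance of a GRKO library from the mean of its group's others was 1.1 ± 0.18 (root mean square of log2 CPM, SD, n = 6) at 6 months and 0.93 ± 0.063 (n = 6) at 3 months, with a two-sided exact permutation p of 0.013 and 0.0173 after adjustment over 4 such comparisons. Each distance uses the other libraries of its group, so the permuted distances are not independent. This p and those below are therefore approximate. Without GRKO library 12 the 6 months mean was 1.03 ± 0.1 (n = 5) and the exact p was 0.0541, so the difference may rest on that library. In WT the order was the opposite, with 1.14 ± 0.08 (n = 6) at 6 months and 1.47 ± 0.19 (n = 5) at 3 months (exact permutation p = 0.00216, adjusted 0.00432). That WT order went with the 3 months libraries that stood apart: correlations of library 2 or 6 with 10, 12 or 13 were 0.7645 to 0.801, against 0.938 between 2 and 6 and 0.914 to 0.939 among 10, 12 and 13. It therefore does not show that WT ovaries grew more alike with age.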
